A study of Homo sapiens with 2 samples.

How the data were processed

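Gene expression was measured on 2 two-channel oligonucleotide arrays of 37632 spots in 48 print blocks. Each carried RNA of HepG2 cells treated with hawk tea extracts (200 µg/mL, 24 h) in 1 dye and RNA of DMSO-treated cells (1‰) in the other, with the dyes swapped between replicates, per the labels. The labels name 1 group with replicates 1 and 2. They give total RNA, amplification and dye incorporation by Klenow enzyme, per the labels' protocols. A sample code inside 1 deposited sheet differs from the labelled treatment, and the labels were followed. Both arrays carry the same order code in their deposited names, which does not settle whether the same extracts were used on both.

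Spot and local background intensity in both channels (635 nm for Cy5, 532 nm for Cy3) was deposited as LuxScan output, per the file headers, with no normalization. The deposited files also hold background-subtracted intensities, their Cy5 over Cy3 ratio, and the log10 of that ratio, per the file headers. The scanner's spot call has 2 levels and was read as found (100) or not found, since 527 of 528 blank and solvent spots had the second level on each array. That reading is uncertain, because 4278 and 5457 gene spots brighter than the blank spots in both channels also had the second level and the files hold no legend for it. The authors' value table holds 1 ratio per spot and array. Its unit, scale and direction are not given in the sources used here. Over 4174 spots found on both arrays its log2 followed treated over DMSO with r of 0.96 on replicate 1 and 0.96 on replicate 2, and its medians were 1.03 and 1.00, so it was read as a linear ratio of treated over DMSO centred near 1. How the authors normalized it stays unknown.

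From the scanner intensities, spot medians were corrected with background medians by normexp with an offset of 50, and log2 ratios were normalized within each array by loess (span 0.3) with weight 0 for control spots and spots not found. Ratios were turned to treated over DMSO from the dyes in the labels. The 8 yeast control features, each with 48 spots, had the same sign on both arrays after turning (6 lower, 2 higher with the treated RNA), with r of 0.99 between arrays. Their log2 ratios were large, from -3.80 for Y6 to 1.42 for Y5 on replicate 1 and from -4.27 to 0.86 for the same 2 on replicate 2, for reasons not given in the sources used here. They were not used in normalization, since their input amounts are not given in the sources used here. The human control features, each also with 48 spots, agreed less. Median log2 ratios on replicates 1 and 2 were -0.44 and 0.22 for GAPD and -0.18 and 0.07 for ACTB. They were -0.32 and -0.46 for LDHA and 0.20 and 0.06 for RPS9. The main filter kept probes found by the scanner on both arrays. Of 36164 gene spots, 26320 had a name and 9844 had none. Names were updated through the RefSeq gene table of GRCh38.p14, used for names only. Of the named spots 18651 carried a current symbol, 4601 were matched to 1 through an older name or accession, and 3068 kept the name in the file. The array names 19826 different genes, of which 3298 were tested, 2964 of them under a current symbol. For the 265 genes with more than 1 found probe the brightest was used. Among the named genes the probes of NOP56 (-1.88 and -0.70) and of NPM1 (7 probes, from -0.76 to -0.36) differed most. No coordinates are given because the files name no genome build.

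The median signal over background of found spots was 46.6 times the 95th percentile of blank and solvent spots in Cy5 and 8.79 times in Cy3 on replicate 1, and 62.8 and 15.3 times on replicate 2. Scanner signal was saturated in 1 gene spot on replicate 1 and 0 on replicate 2. A probe not above that percentile on either array of a condition has only a bound there. The bound was the mean normalized log2 signal of the other condition against, per array, the higher of the probe's own signal and the lowest signal above the blanks, per channel after loess and Aquantile.

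Mean ratios were tested against 0 with lmFit and eBayes in limma 3.58.1 (R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over 3298 genes and a threshold of 0.05. The prior degrees of freedom were infinite, so all genes shared a variance (SD of 1 array 0.32). Beside the test, genes at least 2-fold on both arrays in 1 direction were counted. For 33 gene lists fixed before the data were examined, camera was run with a preset correlation of 0.01 on the 31 lists with at least 3 measured genes, with Benjamini-Hochberg adjustment. Its calls were set beside camera with an estimated correlation and fry, which tests a list's own genes and does not compare them with others. The estimated correlation and fry both rest on 1 residual degree of freedom, too few to decide about a list. Failing with either therefore counts neither for nor against a list. Of 31 lists 16 passed with the preset correlation, 9 higher and 7 lower, while 0 passed with an estimated correlation (smallest adjusted p 0.49) and 0 by fry, or 3 by fry in either direction. Without adjustment 0 of 31 lists had p under 0.05 with an estimated correlation and 11 had by fry.

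Genes were named by a rule fixed before the data were examined. It takes the 12 highest and 12 lowest genes by the smaller of the 2 arrays' log2 ratios, among those past the threshold with 1 direction and an official symbol. It adds per list up to 4 passing members with the largest mean ratio, or the largest 2 where none passed, and 12 genes of lipid, bile acid, xenobiotic and liver function named in advance. Some genes that this rule takes are not reported here.

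The pipeline was tested on simulated arrays with the real intensities and dye curves, in which 200 of 3298 genes were changed. Of genes changed by a log2 ratio of 0.5, 9.0% (6 of 67) were recovered, of those changed by 1, 76.1% (51 of 67), and of those changed by 2, 100% (66 of 66). Of 125 genes called, 2 (1.6%) had not been changed. The simulated noise was independent between genes and had the same SD (0.32) for all of them, as the fit assumes. The share of false calls therefore does not apply where genes differ in spread. In the list simulation below no gene outside the moved list was changed, unlike in the data. A simulated list of 12 genes moved by 1 among 3298 gave a camera p of 4.26e-55, or p = 0.038 with an estimated correlation, and an unmoved list of 12 gave p = 0.37.

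Alternatives fixed in advance were no background subtraction, the scanner's subtracted signals, a normexp offset of 16, median centring, loess followed by Aquantile, the 4 channels as separate samples, no filter, a stricter filter, the mean over probes, the authors' value table, eBayes with trend and robust, other thresholds, leaving out each replicate, an estimated correlation and fry. Chosen after seeing the data were a filter on blank spots, spot means, loess on all gene spots, loess per print block, no moderation, and averaging the arrays as 1 replicate. For the separate samples the channels were quantile normalized without loess, and the fit ignored which channels shared an array. Figures were drawn with matplotlib 3.10.9.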

Results

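The data were 2 two-channel microarrays on which RNA of HepG2 cells exposed to hawk tea extracts was hybridised against RNA of HepG2 cells given the solvent alone. HepG2 is an established human hepatocellular carcinoma line that keeps many functions of liver cells. Hawk tea is a herbal infusion made from the leaves of trees of the laurel family. Cells received 200 µg/mL of extract for 24 h, and control cells received DMSO at 1‰. The dyes were swapped, so that the treated RNA carried Cy5 on replicate 1 and Cy3 on replicate 2, and all ratios below are treated over DMSO. Each array held 37632 spots, of which the scanner software found 6186 (16.4%) on replicate 1 and 6929 (18.4%) on replicate 2. Probes found on both arrays gave 3298 named genes for the test. The number of arrays limits the precision, and with the spread pooled over genes each mean log2 ratio had a standard error of 0.22 (n = 2 arrays). The labels do not say whether the arrays held separate cultures or a dye swap of the same extracts. The p-values therefore measure only the spread between these arrays, which may be technical.

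The comparison asked which genes differ in expression between extract-treated and solvent-treated HepG2 cells. The gene with the highest ratio was IGFBP1, a secreted binding protein of insulin-like growth factors, at a mean log2 ratio of 3.51 ± 0.22 (SE, n = 2 arrays), or 11.4-fold. It was followed by NT5DC4 at 2.53, the growth factor AREG at 2.28, MVP, the main protein of vault particles, at 2.15, LGALS1, a galactose-binding lectin, at 2.07, POLD4, a DNA polymerase delta subunit, at 2.07, and DHCR7, the last enzyme of cholesterol synthesis, at 2.03. NPM2 rose by 1.87, ASNS by 1.75, SERINC2 by 1.73 and PRAP1 by 1.73. The lowest ratio belonged to CYP24A1, which degrades active vitamin D, at -3.02, although its replicates differed widely, at -1.92 and -4.12. DKK1, a secreted Wnt inhibitor, stood at -2.65, GSTA1, a glutathione transferase of the liver, at -2.57, RRM2, a subunit of ribonucleotide reductase, at -2.45, HAMP, which encodes the iron hormone hepcidin, at -2.40, and ID1, an inhibitor of DNA-binding transcription factors, at -2.05. In DMSO, NT5DC4 exceeded the blank spots on 1 of the 2 arrays, and CYP24A1 did so in treated cells on 1 of 2. The size of both ratios is uncertain, with NT5DC4 at 3.81 and CYP24A1 at -6.66 by the scanner's subtracted signals, and NT5DC4 at 4.57 and CYP24A1 at -5.73 in the authors' value table.

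In all, 727 of 3298 genes (22.0%) changed by limma's moderated test with Benjamini-Hochberg adjustment, 363 higher and 364 lower. The smallest mean log2 ratio called was 0.57 in size. IGFBP1 had an adjusted p of 1.26e-49, and the largest among the 12 highest and 12 lowest genes was 2.34e-12, for PRAP1. At least 2-fold changes in 1 direction on both arrays were seen for 122 genes, 69 higher and 53 lower, and 0 of the 3298 genes read at least 2-fold in opposite directions on the 2 arrays, against 76 of 19826 with no filter on spots and 2 with the authors' value table. Across genes, which are not independent replicates, the ratios of the 2 arrays correlated with Pearson's r of 0.69 and Spearman's rho of 0.60, and 2283 genes (69.2%) had the same sign on both. Among the changed genes 2 had opposite signs, MRPS17 and R3HDM2, which are named here after their values were seen. The count of changed genes was 412 with median centring in place of loess, 38 with the 4 channels as separate samples and 53 with no filter on spots, and 0 without moderation of the variance, where 344 genes had an unadjusted p under 0.05. Of 99 named genes past the test, 72 lost the call with separate channels and 70 with no filter. The separate-channel fit ignored which channels shared an array and used no loess, so differences between arrays enter its error. Calls lost with it therefore do not bear on the paired ratios alone. A 2-array design cannot go below p = 0.5 in an exact sign-flip permutation test of a single gene.

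**Figure D1:**
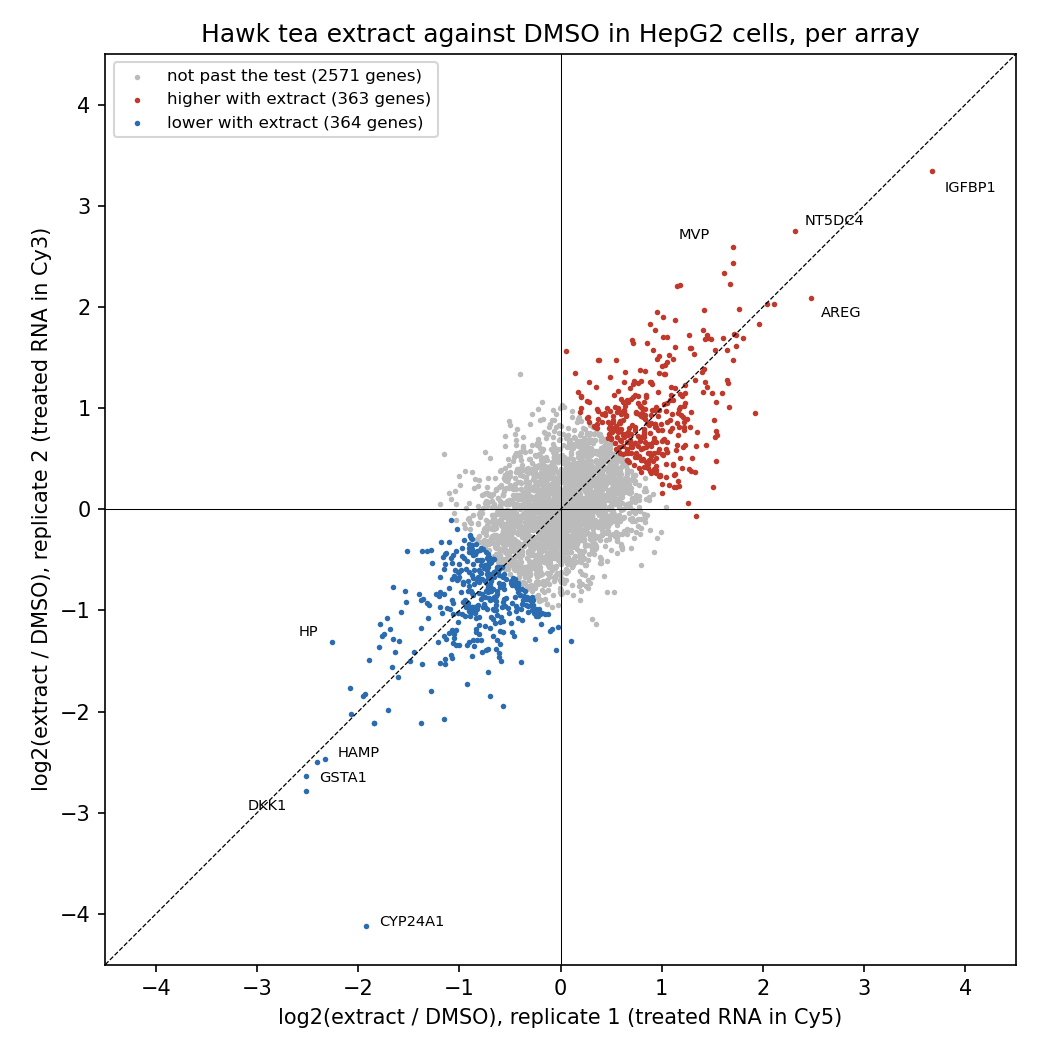
Log2 ratio of extract over DMSO on replicate 1 (horizontal axis) against replicate 2 (vertical axis), 1 point per gene for 3298 genes, with the 363 higher genes in red, the 364 lower genes in blue and the others in grey; the dashed line marks equal ratios. IGFBP1 lies at 3.67 and 3.34 in the upper corner, and CYP24A1 lies off the dashed line at -1.92 and -4.12.

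Genes of the cell cycle were lower in treated cells. Of the 10 measured genes of the list for DNA replication and the G1/S transition, 9 fell and 0 rose, with a list median of -1.26. They included RRM2 at -2.45, the replicative helicase subunit MCM2 at -1.51 and the clamp loader subunit RFC4 at -1.48. Of 12 measured genes of mitosis and G2/M, 10 fell and 0 rose, with a median of -1.44. Cyclin A2 (CCNA2) stood at -1.90, cyclin B1 (CCNB1) at -1.85, and the mitotic kinases PLK1 and AURKA at -1.69 and -1.63. Adjusted over the list alone, the counts were the same 9 and 10. Both lists were lower than the other genes by camera with a preset correlation of 0.01, at adjusted p = 1.15e-12 and 1.13e-12. With an estimated correlation, which rests on 1 residual degree of freedom and so cannot decide, the adjusted p was 0.49 for both. AURKA read 0.20 when spots the scanner had not found were admitted, since another probe of it is then the brightest. Of 3 measured replication-dependent histone genes 1 fell, H4C3 at -1.02, also adjusted over the list alone, and the list did not pass (adjusted p = 0.35).

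Genes of lipid metabolism rose in 3 lists. Of 7 measured genes of cholesterol synthesis and uptake, 4 rose, DHCR7 at 2.03, SQLE, a monooxygenase that acts on squalene, at 0.94, FDPS at 0.83 and ACAT2 at 0.67. With separate channels FDPS stood at 1.35 (adjusted p = 0.061) and ACAT2 at 1.02 (adjusted p = 0.12), and ACAT2 at 1.05 in the authors' value table. Of 10 measured genes of the list for fatty acid and triglyceride synthesis (SREBP1 and LXR targets), 6 rose. Among them were the desaturases FADS1 at 1.65 and FADS2 at 1.08, PNPLA3, a lipid droplet protein, at 1.15, and TMEM97 at 0.70. Of 10 measured genes of the list for fatty acid oxidation and ketone synthesis (PPARA targets), 6 rose. Among them were the lipid droplet protein PLIN2 at 1.50, the fatty acid binding protein FABP1 at 1.03 and ACADVL, the first dehydrogenase of very long chain oxidation, at 0.91. As the lists also hold targets of these regulators, a member need not be an enzyme of the pathway named. None of the measured genes of these lists fell. Adjusted over the list alone, 4, 6 and 7 rose. The camera adjusted p was 0.0036, 0.00011 and 0.00056, and 0.49 for each with an estimated correlation.

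Of 9 measured genes of lipoproteins and their secretion, 2 rose, APOE at 1.07 and APOC1 at 1.06, while 3 fell, among them APOB, the structural protein of very low density lipoprotein, at -0.96 and APOH at -0.84. APOB read -0.60 on replicate 1 and -1.33 on replicate 2, and the call of APOH was lost with the authors' value table, at -0.48 (adjusted p = 0.15), and with separate channels, at -0.53 (adjusted p = 0.72). Of 4 measured genes of bile acid synthesis and transport, 2 rose, the canalicular export pump ABCC2 at 1.20 and the nuclear receptor NR0B2 at 0.74. Adjusted over the list alone, 3 rose and 3 fell in the first list and 2 rose in the second. Neither list passed camera in the main setting, at adjusted p = 0.46 and 0.066. The bile acid list passed it under an alternative setting (lowest adjusted p 0.0498).

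Stress genes moved in both directions. Of 12 measured targets of ATF4 in the integrated stress response, 7 rose, among them ASNS, asparagine synthetase, at 1.75, the pseudokinase TRIB3 at 1.68, SESN2 at 1.46 and the transcription factor ATF3 at 1.01, which read 0.54 on replicate 1 and 1.47 on replicate 2. Of 17 measured genes of the NRF2 antioxidant response, 8 rose, among them ABCC2 at 1.20, the autophagy receptor SQSTM1 at 1.14, BLVRB, a biliverdin reductase, at 1.11 and HMOX1, heme oxygenase 1, at 0.94. Of 9 measured genes of autophagy and lysosomes, 6 rose, among them GABARAPL1 at 1.59, the lysosomal protease CTSB at 1.34 and SQSTM1, which read 1.55 on replicate 1 and 0.73 on replicate 2. In contrast, 3 of 9 measured genes of the endoplasmic reticulum unfolded protein response fell, MANF at -1.10, the chaperone HSPA5 at -0.998 and SDF2L1 at -0.82. Adjusted over the list alone, 7, 9 and 7 rose in the first 3 lists and 5 fell in the last. The 4 lists passed camera at adjusted p = 3.33e-05, 0.000275, 3.62e-05 and 0.017, and none did with an estimated correlation (adjusted p = 0.49 each). In the heat shock list 3 of 11 measured genes fell, the mitochondrial chaperonins HSPE1 at -0.97 and HSPD1 at -0.64 and DNAJA1 at -0.58. With the 4 channels as separate samples HSPE1 stood at -0.07 (adjusted p = 0.95), and HSPD1 at -0.31 (adjusted p = 0.68). In the authors' value table HSPD1 stood at -0.41 (adjusted p = 0.23), and it read -0.22 on replicate 1 and -1.05 on replicate 2. Adjusted over the list alone 5 fell, and that list did not pass in the main setting (adjusted p = 0.063). It passed camera under an alternative setting (lowest adjusted p 0.0066).

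Of 6 measured p53 targets 3 rose and 1 fell, the same counts as adjusted over the list alone. BBC3, a pro-death BCL2 family member, stood at 1.70, GDF15 at 1.45, GADD45A at 0.64 and BAX, another pro-death member of that family, at -0.73. GDF15 read 0.95 on replicate 1, and GADD45A 0.41 on replicate 2. The mean of the list was 0.58, and 0.08 without BBC3 and GDF15. The list passed camera (adjusted p = 0.018), and had an adjusted p = 0.57 with an estimated correlation. Among 6 measured apoptosis regulators HRK rose by 1.24 and BAX fell, 1 gene each way also adjusted over the list alone, and the list did not pass (adjusted p = 0.44). The p53 call was lost with separate channels, with no filter or a filter on blank spots, and with the authors' value table, where the camera adjusted p was 0.085 to 0.26.

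Metallothioneins, small metal-binding proteins, were lower. Of 6 measured genes, 5 fell, also adjusted over the list alone: MT1G at -1.98, MT1E at -1.97, MT1X at -1.92, MT1H at -1.45 and MT2A at -1.14. MT1B, at 0.13, did not pass the test. The sequences of these paralogs are close, so their probes may share transcripts and the values of single members are uncertain. The list passed camera at adjusted p = 1.80e-09 (adjusted p = 0.49 with an estimated correlation). In the list of drug-metabolising enzymes, 3 of 6 measured genes fell and 1 rose, also adjusted over the list alone. The glutathione transferases GSTA1 and GSTA2, likewise close in sequence, stood at -2.57 and -1.61, the glucuronosyltransferase UGT2B7 at -0.58, and POR, the electron donor of cytochromes P450, at 1.19, or 0.70 and 1.67 on the 2 arrays. The mean of the list was -0.49, and 0.30 without GSTA1 and GSTA2, so its shift rested on those 2 probes. In the list for iron handling, 2 of 7 measured genes fell, HAMP at -2.40 and ID1 at -2.05, and HMOX1 rose by 0.94, again the same adjusted over the list alone. The median of that list was -0.13 and its mean -0.54, so its shift rested on HAMP and ID1. The 2 lists passed camera at adjusted p = 0.045 and 0.017 (0.49 each as the adjusted p with an estimated correlation), and both calls were also lost with separate channels, no filter, a filter on blank spots or the authors' table. That of the drug-metabolising enzymes was lost as well with spot means or loess per print block.

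Plasma proteins made by the liver moved both ways. Of 15 measured acute-phase and coagulation proteins, 4 rose and 4 fell. HAMP stood at -2.40, haptoglobin (HP) at -1.79, fibrinogen alpha (FGA) at -1.39, and fetuin A (AHSG) at 1.12. Of 12 measured genes of hepatocyte differentiation, 3 rose and 1 fell, the retinol carrier RBP4 at 0.97, HPD at 0.77, ASS1 at 0.77 and the transcription factor FOXA2 at -0.58, or -1.002 by the scanner's subtracted signals. Adjusted over the list alone, 4 rose and 5 fell in the first list, and 3 rose and 2 fell in the second. Neither passed camera in the main setting, at adjusted p = 0.061 and 0.44. The acute-phase and coagulation list passed it under an alternative setting (lowest adjusted p 0.0498). Albumin (ALB) had a ratio of 0.17, or 0.37 and -0.03 on the 2 arrays, which did not pass (adjusted p = 0.66).

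Of 4 measured genes of gluconeogenesis and glycogen, 2 rose and 1 fell, also adjusted over the list alone. IGFBP1, which is not an enzyme of this pathway, stood at 3.51, PC, pyruvate carboxylase, at 1.16, and FOXO1, a transcription factor, at -1.01. The mean of the list was 0.93, and 0.07 without IGFBP1, so its shift rested on that gene. The list passed camera at adjusted p = 0.0020 (adjusted p = 0.49 with an estimated correlation), and the call was also lost with separate channels, no filter, a filter on blank spots or the authors' table. Of 7 measured genes of extracellular matrix and TGF-beta targets, 3 rose, among them the intermediate filament protein VIM at 0.89 and fibronectin (FN1) at 0.76, the same count adjusted over the list alone. That list passed at adjusted p = 0.0036, with an adjusted p = 0.49 with an estimated correlation, and its call was lost with no filter or a filter on blank spots. Of 12 measured genes of ribosome biogenesis, 4 fell, also adjusted over the list alone. NOP56 stood at -1.88, although its other probe read -0.70, POLR1B at -1.01, NPM1 at -0.76 and WDR12 at -0.61. On replicate 1 POLR1B read -0.64 and WDR12 -0.33, and the call of NPM1 was lost with the authors' table, at -0.49 (adjusted p = 0.14), and with separate channels, at -0.38 (adjusted p = 0.68). That list passed at adjusted p = 0.0094 (adjusted p = 0.49 with an estimated correlation).

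**Figure D2:**
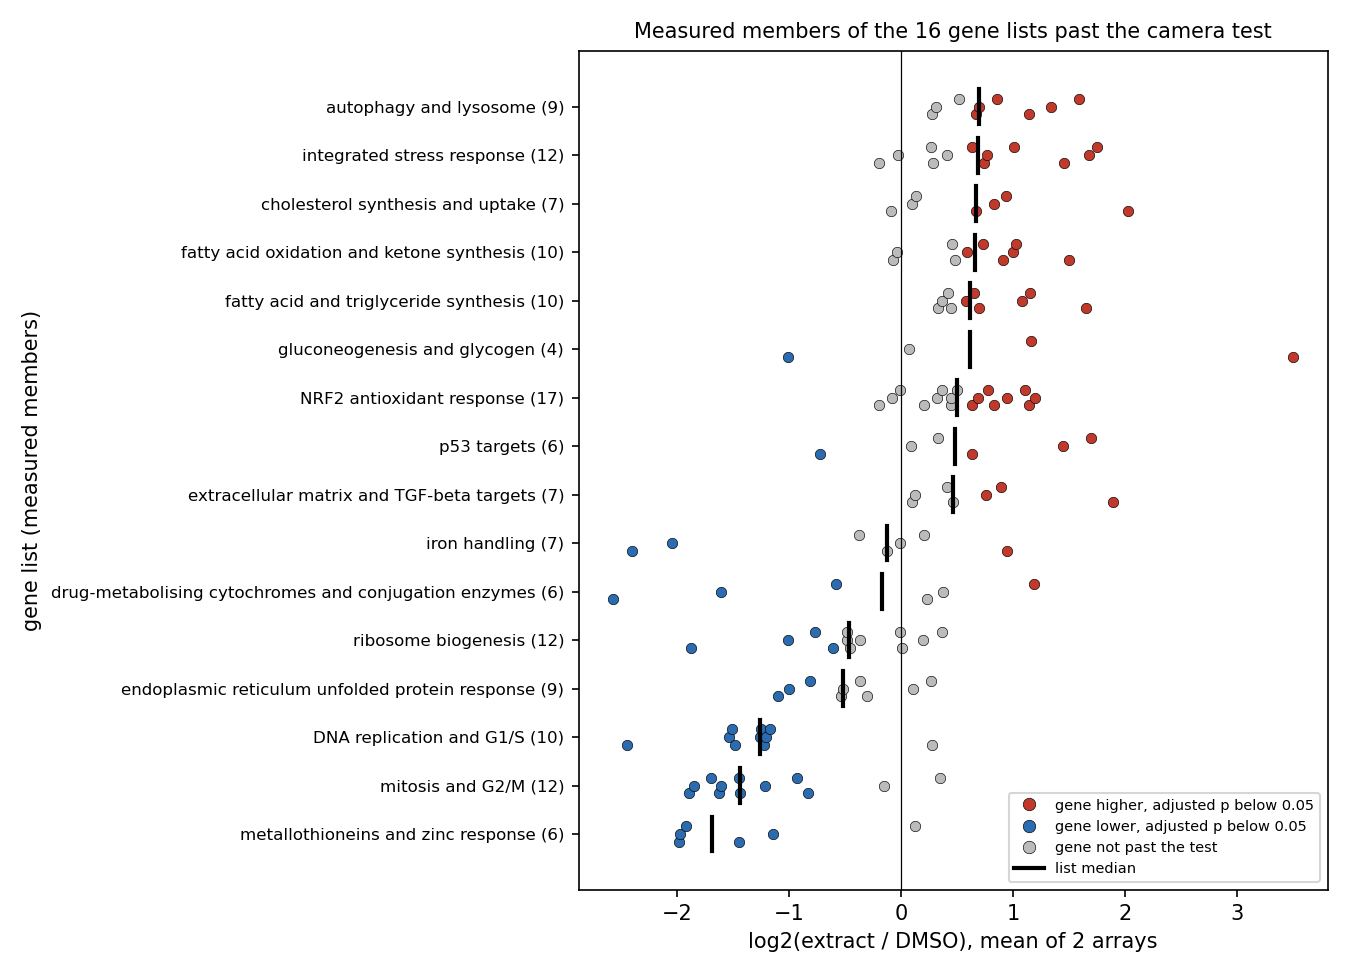
Mean log2 ratio of extract over DMSO over 2 arrays (horizontal axis) of each measured member of the 16 gene lists past the camera test (vertical axis, with the number of measured members); red points are genes that rose, blue points genes that fell, grey points genes not past the test, and black bars list medians. Medians run from -1.69 for metallothioneins to 0.70 for autophagy and lysosome, and in the gluconeogenesis list IGFBP1 stands alone at 3.51.

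The remaining lists did not pass camera in the main setting. Under alternative settings cytosolic ribosomal proteins (lowest adjusted p 0.0055), hypoxia and glycolysis (0.013) and NF-kB targets (0.047) did pass it. Of 25 measured genes of oxidative phosphorylation 2 fell, ATP5MC1 at -0.65 and CYC1 at -0.58, and adjusted over the list alone 0 did. CYC1 stood at -0.32 with separate channels (adjusted p = 0.58). Of 24 cytosolic ribosomal proteins RPL38 rose by 0.70, a call lost with spot means at 0.35 (adjusted p = 0.24), and of 12 genes of hypoxia and glycolysis ALDOC rose by 0.98. Of 3 aryl hydrocarbon receptor targets SLC7A5 rose by 0.64. Of 6 NF-kB and inflammatory targets, C3 at 1.15 and SOD2 at 0.91 rose and CCL20 at -0.73 fell. Of 5 interferon response genes, ISG20 rose, at 1.59, and BST2 fell, at -0.66. Of 7 immediate early genes, ATF3 at 1.01 and JUN at 0.85 rose and DUSP6 at -0.70 fell, and 2 fell adjusted over the list alone. Elsewhere in this group of lists the counts adjusted over the list alone were the same. In the main setting their camera adjusted p values lay between 0.29 and 0.70. Markers of other cell types were hardly measured. CLEC4F, at 0.46, was the only measured blood and immune marker, and it did not pass limma's test over all genes (adjusted p = 0.13). Over the list alone it counts as passing, but with 1 gene that is limma's unadjusted p of 0.041. LUM, at -0.40, was the only measured marker of fibroblasts, stellate or endothelial cells and did not pass either way. Of 4 measured markers of other epithelial lineages 0 passed either way in limma, VIL1 reading 0.44 and EPCAM 0.35, and the list had an adjusted p of 0.46.

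Genes of cholesterol and lipid control that were chosen in advance were often not found by the scanner on both arrays or too dim. FASN, fatty acid synthase, rose by 0.65 and PPARA, a receptor for fatty acids, by 0.73, and PPARA read 0.46 and 1.00 on the 2 arrays. SREBF1 had a ratio of 0.33 that did not pass, and its replicates read -0.29 and 0.94. CPT1A was found on neither array and read 0.98 and 0.04, although it was above the blank spots on 2 arrays in treated cells and 1 in DMSO. CYP7A1 and ABCA1 were not above the blank spots in either condition. CYP1A1 was found on neither array and read -0.09 and -0.43. It was above the blank spots on 1 array in DMSO and on none in treated cells. Its bound was 1.08-fold lower, but this averages in a DMSO signal that was not above the blanks. No fall of CYP1A1 can be read from these values.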

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

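Probes without a gene name in the deposited files were left out of the comparison of named genes. Of 546 such probes found on both arrays, 9 changed at least 2-fold in 1 direction on both, 6 higher and 3 lower in extract-treated cells, and 0 changed 2-fold in opposite directions. By limma's test 52 of the 546 passed, 23 higher and 29 lower, and the ratios of the 2 arrays correlated with r of 0.57 across these probes. Among the named genes 727 of 3298 passed, 122 were at least 2-fold on both arrays, and r was 0.69. Changes of at least 2-fold on both arrays were thus less frequent among the unnamed probes than among the named genes. The counts past the test come from separate fits, each with its own adjustment, and do not compare directly. The unnamed probes are reported because they lie outside the main measurement. No explanation was tested, since the transcripts they detect are not named in the sources used here.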

How the results depend on the processing

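No moderation, spot means, the blank-spot filter, the 2 further loess fits and the averaged arrays were chosen after seeing the data. The 727 changed genes became 412 with median centring (202 higher, 210 lower), 38 with separate channels (26 higher, 12 lower), 53 of 19826 genes with no filter (30 higher, 23 lower), 466 at an adjusted p under 0.01, 199 at 2-fold, and 0 without moderation, where limma is left with 1 residual degree of freedom and 344 genes had an unadjusted p under 0.05. The cause of the lower counts with median centring was not tested. Of the called genes 411 under median centring, 38 with separate channels and 35 with no filter were among the 727, all in the same direction. The blank-spot filter tested 9077 genes and called 867, of which 439 were shared. Separate channels raised the median of all genes to 0.11 and the share of higher calls from 49.9% to 68.4%. The 122 genes at least 2-fold on both arrays became 193 with no filter, 193 with the blank-spot filter (both test more genes), 442 at 1.5-fold, 29 at 3-fold and 199 on the averaged arrays, and 242 to 257 on a single array. The correlation of the arrays, 0.69, was 0.58 with median centring, 0.15 with no filter, 0.55 with the blank-spot filter and 0.71 with loess per print block. The cause of these moves was not tested. Over the 14 camera settings with the preset correlation the 16 lists became 13 to 18, the highest with spot means. They became 0 with an estimated correlation and 0 by fry, which both rest on 1 residual degree of freedom and so cannot decide. Of the 16, 11 kept their call under all 14, and drug-metabolising enzymes, p53 targets, gluconeogenesis, extracellular matrix and iron handling lost it under 2 to 6. Over the 14, other lists gained 10 calls. The list value compared across settings is the mean, a choice made after medians had been seen to change sign. For drug-metabolising enzymes (mean -0.49, median -0.17) the direction of the test reversed with no filter, at a mean of -0.019 and a median of 0.14, and the median was 0.12 with the blank-spot filter. For iron handling (median -0.13) the median was 0.65 with separate channels, 0.17 with the authors' table, 0.06 with median centring and 0.00035 with loess on all gene spots, and for extracellular matrix (median 0.46) it was -0.08 with no filter. The cause was not tested. The lists for aryl hydrocarbon receptor, NF-kB and immediate early genes had medians of -0.05, -0.02 and -0.03 but means of 0.17, 0.16 and 0.08, and none passed. Of 1573 values of 105 named genes under alternatives with a test, 1359 kept direction and side of the threshold, 211 lost the call, 1 gained it and 2 reversed, AURKA at 0.20 with no filter and 0.20 with the blank-spot filter, where a probe the scanner did not find is the brightest. NT5DC4 and CYP24A1 had no value under the stricter filter. Of 210 values on a single array, which have no test, 2 had the other sign, SREBF1 at -0.29 on replicate 1 and ALB at -0.03 on replicate 2, neither past the test on both arrays together. Of the 99 genes past the test, 12 had a value over 1.5 times larger or smaller under an alternative with a test and 11 on a single array. The 12 highest and 12 lowest genes, picked as extremes of these same data, kept their call in 355 of 358 values (largest adjusted p 0.074). Aquantile after loess left all ratios as they were, so it tests nothing. It is still counted, in 105 of the 1359 kept values, the 14 settings and the 358 values. No paired analysis was possible with 1 group, whose ratios already pair treated with DMSO on each array. The scanner's spot call (no legend) limits the comparison to the 16.4% and 18.4% of spots found.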

Other observations

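The tests of dye effects on cell cycle genes and metallothioneins and of cross-hybridisation, and the screen of symbol stems, were chosen after the values were seen, and the tests of spot position, dim spots, HAMP and ID1, and lysosomal genes were set before their results were seen. The genes in the next paragraph that the naming rule does not cover were chosen after their values were seen.

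Outside the fixed lists, several genes changed at least 2-fold on both arrays by limma's test. Calcium-binding S100A6 and S100A11 stood at 1.40 and 1.35, the actin-binding TMSB10 at 1.34, the GTPase RHOC at 1.43, EMP3 at 1.69, SDC4, a cell surface proteoglycan, at 1.67 and UCHL1, a deubiquitinase, at 1.33. The related BEX1 and BEX2 stood at 1.30 and 1.08. TUBB2B, whose probe may be shared with close tubulin paralogs, stood at 1.95. Lower genes included GINS4, a component of the replicative helicase, at -1.75, the chromatin proteins HMGB2 and HMGB1 at -1.36 and -1.19, the microtubule regulator STMN1 at -1.28, the histone chaperone NASP at -1.14, and EPO, the hormone erythropoietin, at -1.31. A screen of 67 groups of at least 5 genes that share a symbol stem gave 0 groups past an adjusted p of 0.05 by camera (smallest 0.27), 7 at an unadjusted p under 0.05, and 0 by fry or with an estimated correlation after adjustment.

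The lower cell cycle genes were set against 3 technical explanations. A gene-specific dye effect would give opposite signs after the swap, but 20 of 22 measured members (90.9%) had the same sign on both arrays. The lists, fixed beforehand, were taken up here for their low means over the swapped arrays. Members of such lists would largely share signs anyway, so this count is weak evidence. An effect of spot position would shrink with a loess curve per print block, but the median was -1.36 with it and -1.35 without. Background subtraction in dim spots would spare bright members, but the 9 members brighter than the median tested gene had a median of -1.21. A difference between 1 pair of cultures stays open, as the labels do not say that the arrays hold separate cultures.

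The lower metallothionein probes were set against 2. A dye effect would give opposite signs, and 6 of 6 members (100%) had the same sign on both arrays. This count is weak evidence too, since the list, fixed beforehand, was taken up here for its low mean over the swapped arrays. If 1 transcript cross-hybridised to all probes, members would share a ratio, but the highest (MT1B) and lowest (MT1G) differed by 2.11, against 0.63 for 2 standard errors of a difference, and were ordered alike on both arrays. Leaving out MT1B, a step added after the result, the gap was 0.84, or 0.80 and 0.88 per array. That gap lies between members picked as extremes, while 0.63 holds for 2 genes fixed beforehand, so it cannot decide. Sharing of signal among the 5 lower members stays possible, and so does a difference between 1 pair of cultures.

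HAMP and ID1 are both known targets of bone morphogenetic protein signalling through SMAD proteins, so a fall of that pathway is a candidate explanation for their joint fall. Of the 15 other targets listed before the test, 1 was measured, MSX1 at -0.21, which did not pass, and this leaves the hypothesis undecided because at least 3 were needed.

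The rise in the lysosome list might extend to other lysosomal genes. Of the 39 other genes listed before the test, 15 were measured, with a median of 0.37, or 0.12 and 0.48 on the arrays. Of these 3 rose, PSAP at 1.26, NPC1 at 1.23 and GAA at 0.66, and 0 fell. Camera gave p = 0.060, or p = 0.29 with an estimated correlation, so the values do not decide whether the rise is shared by lysosomal genes at large.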
